A study of Homo sapiens with 11 samples.

How the data were processed

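Peak lists from ChIP-seq in the human Ewing sarcoma line SK-N-MC were used, 9 in all, 1 for each of CHD4, HDAC2, MTA2, RBBP4, FLI1, H3K27ac, H3K4me1, H3K4me3 and H3K27me3. The 2 input libraries had no list and were not analysed here. Samples were grouped by the target in their labels.

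Reads were processed with Trimmomatic 0.36, FastQC 0.11.7, BWA 0.7.17, SAMtools 1.9, deepTools 3.2.1 and bedtools 2.27.1 on GRCh38, per the submitters' processing notes. The peaks carry MACS2 in their names, per the deposited peak names, and its version is not given in the sources used here. Which control library was used, whether replicates were pooled and which regions were excluded are not given in the sources used here either. Each peak has a fold enrichment at its summit over the local background, a ratio computed by the authors' peak caller, and a −log10 p and −log10 q, also as deposited. The deposited score of each peak was not used. These values belong to the authors' lists and served only to rank, filter and describe peaks within a list. In 6 lists the peak numbers have gaps, from 13 missing numbers in the FLI1 list to 213 in the H3K4me3 list, and the reason is not given in the sources used here. The smallest −log10 p was about 9 in 7 lists, 7.01 for RBBP4 and 5.02 for FLI1. The files give no read counts, so depth is unknown, and sites missed for lack of depth cannot be told from sites without the protein. Regions present in extra copies reach a given −log10 p at a lower fold enrichment, which moves both peak number and rank.

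Positions were converted to 1-based coordinates of GRCh38. Peaks shared at least 1 bp to count as overlapping. Peaks of the 4 subunits that overlapped were merged into NuRD sites. Genes came from a RefSeq gene table of the same build with 19974 protein-coding genes. This table gives no strand, so transcription start sites could not be placed, and the planned promoter window became 1 kb around either annotated end of a gene. The shares near gene ends thus count both starts and ends of genes. The nearest gene was the one with the nearest annotated end. No genome sequence was used here, so the planned search for GGAA repeats under FLI1 peaks and the comparison of repeat and other FLI1 peaks were not run.

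Overlap was compared with 1000 random placements that kept chromosome and width, in windows of 1 Mb holding any gene or peak. Such placements also fall in unmarked chromatin, so lists that only share a preference for marked chromatin exceed them too. A share was called higher or lower when at most 5% of placements were as far out on that side. Peaks are not replicates, so the placements, shufflings and draws describe these lists and not the spread between cultures. H3K27ac peaks were divided into 5 groups by fold enrichment and the groups shuffled 10000 times. Subunit heights were compared with 10000 draws. Distal H3K27ac peaks were stitched within 12.5 kb, ranked by summed fold enrichment times width, and called large beyond the point where the scaled rank curve reaches slope 1. The 13 gene lists (224 entries, all 224 matched by symbol) were written from literature and textbook knowledge: genes activated and repressed by EWSR1::FLI1, Ewing core factors, NuRD subunits, HOX, developmental regulators, neural crest and neuronal, mesenchymal, muscle, blood, epithelial, housekeeping, and DNA damage and cell cycle genes. Each was compared with 10000 random lists, two-sided, and Benjamini-Hochberg adjustment covered the 117 list and target combinations, and separately the 13 lists for FLI1 within 100 kb. Calls were made at an adjusted p under 0.05.

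The genes and regions named were set by rule before the data were examined: the 10 FLI1 peaks of highest −log10 p, the 10 sites with all 4 subunits of highest mean rank of fold enrichment, the 10 highest-ranked large domains, the 10 H3K27me3 regions (peaks merged within 5 kb) of greatest covered length, list members with the strongest FLI1 peaks within 100 kb, up to 10 per list, and up to 10 members of other lists. CHEK2, GADD45A, PARP1, MTA1, MTA3, HOXC4, HOXC5 and HOXC6 were named after their values were seen. Members of other lists were taken in alphabetical order, some members are not reported here, and the nearest gene end stood in for the planned start site.

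Local background was recovered per peak by solving for the Poisson mean that gives the deposited fold enrichment, with 1 added to pileup and background, and the deposited −log10 p. This assumes the usual MACS2 definitions. On 1995 peaks simulated under the same definitions the median ratio of recovered to true background was 1.001. This checks the solving and not whether the deposited values follow these definitions. In 40 simulated FLI1 lists with 2% of peaks planted on HDAC2 peaks the overlap was called in 40, and in 40 lists with none planted in 2. Of 500 random lists of 35 genes 2.80% had an unadjusted permutation p under 0.05, and 87.4% with 20% of members planted near FLI1. The reported list calls used the adjusted p, so these rates do not describe them. Of 300 simulated sets of 21500 H3K27ac peaks 2.67% were called with no trend, and 100% with a rise of 5 points.

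Alternatives fixed before the data were examined were a −log10 p of at least 9 or 15 in every list, the 2000 strongest peaks per list, a summit inside or an overlap of at least 50% of the shorter peak, placement within marked chromatin, autosomes only, windows of 500 and 2500 bp, −log10 p as the height, 3 other ways of stitching, and FLI1 within 50 and 250 kb. The restriction to gene ends with H3K4me3 and the removal of chromosome 8 were chosen after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.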

Results

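Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in SK-N-MC, an established human Ewing sarcoma cell line that carries the EWSR1::FLI1 fusion. The series held 11 samples. They were 1 sample each for CHD4 (pulled down through a Flag tag), HDAC2, MTA2, RBBP4, FLI1, H3K27ac, H3K4me1, H3K4me3 and H3K27me3, plus 2 input libraries. CHD4 is the ATPase of the nucleosome remodelling and deacetylase (NuRD) complex, HDAC2 a histone deacetylase in it, MTA2 a scaffold subunit and RBBP4 a histone-binding subunit that other chromatin complexes also contain. FLI1 antibodies recognise the DNA-binding part of the fusion. H3K27ac marks active promoters and enhancers, H3K4me1 enhancers, H3K4me3 promoters and H3K27me3 Polycomb-repressed chromatin. The CHD4 sample was labelled wildtype and how its tag was introduced is not given in the sources used here, so its peaks are those of tagged CHD4, whose level beside untagged CHD4 is unknown. Each of the 9 targets had 1 peak list and the read depth behind the lists was unknown, so no value below has a replicate error. Intervals in brackets are 95% Wilson intervals, which cover counting error over peaks only.

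HDAC2 had the longest list of the 4 NuRD subunits, with 20633 peaks, against 13288 for CHD4, 13462 for MTA2 and 13725 for RBBP4. FLI1 had 1561 peaks. Among the histone marks, 31247 peaks were called for H3K4me1, 21500 for H3K27ac, 16089 for H3K4me3 and 3420 for H3K27me3. Median peak width was 281 bp for FLI1, 274 to 449 bp for the NuRD subunits and 1200 bp for H3K4me3. The smallest −log10 p in a list was 9.003 for CHD4, 7.01 for RBBP4 and 5.02 for FLI1, so list lengths do not measure how many sites each protein occupies. With a −log10 p of at least 15 in every list, RBBP4 kept 6386 peaks, FLI1 972, H3K27me3 1341, CHD4 8796 and H3K4me1 19953.

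The first comparison asked how far the 4 NuRD subunits occupied the same places. Of the MTA2 peaks, 73.4% (72.7 to 74.1) overlapped an HDAC2 peak, as did 72.1% (71.4 to 72.9) of the RBBP4 peaks and 63.5% (62.6 to 64.3) of the CHD4 peaks. CHD4 peaks overlapped RBBP4 in 61.8% and MTA2 in 54.2%. HDAC2 peaks overlapped CHD4 in 38.8%, the lowest of the 12 ordered pairs. Over the 12 ordered pairs, summits of overlapping peaks were a median of 45 bp (MTA2 to RBBP4) to 88 bp (CHD4 to HDAC2) apart, a distance that the required overlap of narrow peaks itself keeps short and that was not compared with chance. When each list was placed at random on its own chromosomes 1000 times, 0.367% to 0.799% of peaks overlapped, and no placement reached the observed share for any pair. The overlaps were therefore 74.9 to 149 times the mean of the placements. These ratios do not tell shared sites from a shared preference for marked chromatin. With peaks and placements confined to chromatin with H3K27ac, H3K4me1 or H3K4me3, the call was kept in the 1 direction rerun for each pair. With the 2000 strongest peaks of each list CHD4 overlapped HDAC2 in 36.95% and MTA2 in 33.4%, and MTA2 overlapped RBBP4 in 35.9% instead of 54.1%, while at a −log10 p of at least 15 HDAC2 overlapped RBBP4 in 27.1% instead of 44.4%.

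Merging the 4 lists gave 28995 NuRD sites, of which 4917 (16.96%) held all 4 subunits. A further 4090 sites held 3 subunits, 6758 held 2 and 13230 held 1. The name NuRD site covers any merged site with at least 1 subunit, so it does not show that the whole complex was present. HDAC2 alone made up 7126 sites, and 57.4% of these overlapped H3K4me3. CHD4 alone accounted for 2493 sites with H3K4me3 at 8.46%. The 1661 sites with HDAC2 and RBBP4 but neither CHD4 nor MTA2 overlapped H3K4me3 in 86.9% and H3K4me1 in 3.67%. Random placement of the 4 lists gave a mean of 14.5 sites with all 4 subunits and at most 19. The number of such sites depended on list length: it was 2683 at a −log10 p of at least 15 and 364 with the 2000 strongest peaks of each list.

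The position of the peaks relative to genes was described next. H3K4me3 peaks lay within 1 kb of an annotated end of a protein-coding gene in 74.1% (73.4 to 74.7) and H3K27ac peaks in 40.6% (39.95 to 41.3). HDAC2 was the subunit most often near gene ends, at 39.1% (38.5 to 39.8), followed by RBBP4 at 31.7% (30.9 to 32.4), MTA2 at 28.4% (27.6 to 29.1) and CHD4 at 16.2% (15.6 to 16.8). FLI1 peaks were near gene ends in 8.78% (7.47 to 10.3), H3K27me3 in 17.5% and H3K4me1 in 5.43%. Sites with all 4 subunits were near gene ends in 20.5% (19.4 to 21.7), against 36.0% of sites with a single subunit. All 9 lists lay near gene ends more often than in each of 1000 placements. The FLI1 share fell to 3.09% at a −log10 p of at least 15 and then no longer stood apart from its placements. With the 2000 strongest peaks of each list, MTA2 was near gene ends in 36.3%, HDAC2 in 29.3%, RBBP4 in 14.4% and CHD4 in 9.40%, so the order of the subunits changed. The share was 8.52% for sites with all 4 and 61.1% for H3K27ac in that setting. It was 9.33% for H3K27me3 when only gene ends with H3K4me3 counted, and for H3K4me1 it ranged from 1.82% to 10.6% over the alternatives.

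The chromatin at NuRD sites was compared by the number of subunits. H3K27ac overlapped 35.02% (34.2 to 35.8) of sites with 1 subunit, 47.0% with 2, 54.1% with 3 and 62.8% (61.4 to 64.1) with all 4. H3K4me1 overlapped 19.5% (18.8 to 20.2) of sites with 1 subunit, 24.4% with 2, 30.2% with 3 and 53.4% (52.0 to 54.8) with all 4, and this order did not hold under stricter overlap. With the site's midpoint inside the mark the H3K4me1 shares from 1 to 4 subunits were 11.97%, 9.75%, 8.44% and 9.31%, and with an overlap of 50% they were 12.1%, 10.5%, 10.1% and 15.8%. The H3K27ac shares still rose in order, from 26.1% to 40.7% with the midpoint rule and from 27.1% to 48.6% with an overlap of 50%. H3K4me3 overlapped 42.8% of sites with 1 subunit and 30.0% (28.7 to 31.3) of sites with all 4. H3K27me3 peaks were rare at NuRD sites, at 0.522% (0.412 to 0.659) with 1 subunit and 0.0814% (0.0316 to 0.209), or 4 of 4917 sites, with all 4. The H3K27me3 peaks covered only 2.38 Mb, against 18.5 Mb for H3K27ac, so sites outside them may still carry the mark. H3K27ac, H3K4me1 and H3K4me3 exceeded all 1000 placements in every class of site. H3K27me3 was above all placements at sites with 1 subunit (placed mean 0.152%) and with 2 subunits (0.370%, placed mean 0.174%), and at HDAC2 peaks (0.494%, placed mean 0.181%). It was below the placements at CHD4 peaks (0.0903%, placed mean 0.181%, 2 of 1000 as low), while MTA2 peaks (0.126%, 146 as low), RBBP4 peaks (0.117%, 82 as low) and sites with 3 subunits (0.293%, 114 as high) did not stand apart. The H3K27me3 share at sites with all 4 subunits was lower than the placed mean of 0.239%, and 13 of 1000 placements were as low. That difference was lost at a −log10 p of at least 15, as was that of CHD4 peaks (0.0796%), and when the site's midpoint had to lie inside the mark, as was that of sites with 2 subunits (0.148%). With a summit inside the mark or an overlap of 50% the low share at MTA2 peaks passed (0.0594% and 0.0743%), and at a −log10 p of at least 9 that at RBBP4 peaks did (0.0933%). Merged sites with more subunits were also wider, with a median of 292 bp for 1 subunit and 786 bp for all 4, which by itself raises the chance of an overlap.

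**Figure D1:**
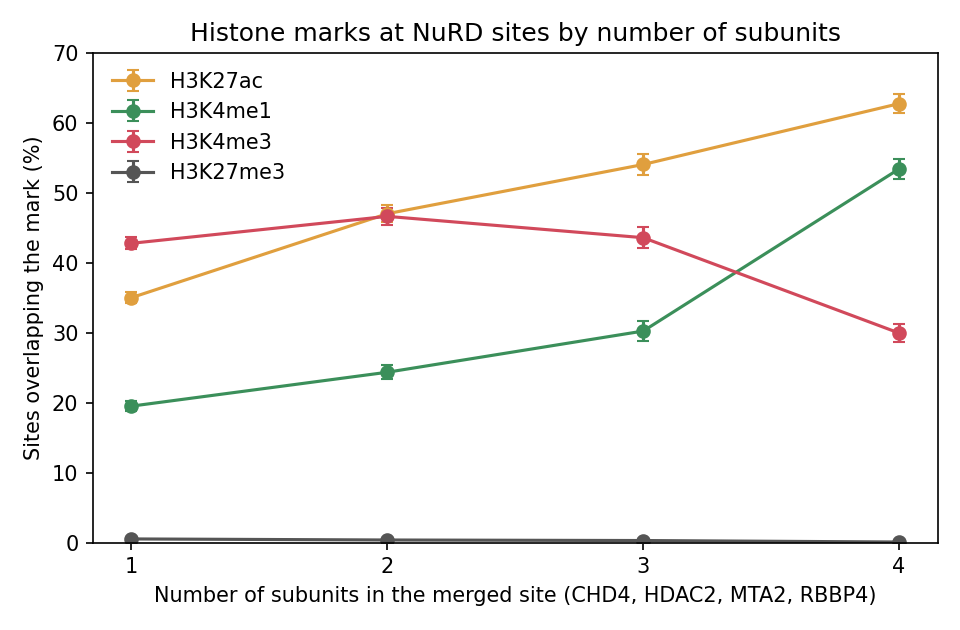
Share of merged NuRD sites (vertical axis, percent) that overlapped each histone mark, by the number of subunits in the site (horizontal axis); points are shares and bars are 95% Wilson intervals. At an overlap of 1 bp H3K27ac rose from 35.02% to 62.8% and H3K4me1 from 19.5% to 53.4%, while H3K4me3 was lowest, at 30.0%, in sites with all 4 subunits; with the site's midpoint inside the mark H3K27ac rose from 26.1% to 40.7% and H3K4me1 went from 11.97% to 9.31%.

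Sorted into chromatin classes, 35.8% (34.4 to 37.1) of sites with all 4 subunits were active enhancers (away from gene ends, with H3K27ac and without H3K4me3), against 10.9% (10.4 to 11.4) of sites with a single subunit. Active promoters (near a gene end, with H3K4me3 and H3K27ac) made up 15.8% (14.8 to 16.8) of sites with all 4 and 18.1% of sites with 1. Primed regions, with H3K4me1 as the only mark and away from gene ends, made up 19.5% and 11.8%. No mark was found at 12.8% (11.8 to 13.7) of sites with all 4 and 33.2% (32.4 to 34.0) of sites with 1. Bivalent sites, with H3K4me3 and H3K27me3, numbered 4 among sites with all 4 and 44 among sites with 1. These classes rest on an overlap of 1 bp with each mark and carried no test.

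The sites with all 4 subunits and the highest mean rank of fold enrichment lay away from gene ends, apart from a site 0.787 kb from an end of XG, a gene known to be activated by the fusion. The highest was inside PLCXD3 (chromosome 5, 41311827 to 41313414, GRCh38), with a fold enrichment of 10.5 for CHD4, 14.2 for HDAC2, 15.97 for MTA2 and 10.6 for RBBP4. Next were a site 24.8 kb from DZIP3 (chromosome 3, 108719058 to 108720291) and a site inside BCAS1 (chromosome 20, 53959684 to 53961998). The others lay inside ZNF804A and CAST (with ELL2 as the nearest gene end), and outside genes nearest to MBL2, SPATA31C2, SLITRK1 and ALX1, the last a homeobox transcription factor. A FLI1 peak overlapped each of these 10 sites except the site in ZNF804A, and an H3K4me1 peak overlapped all 10. FLI1 was present at 70% of the 100 strongest sites with all 4 subunits, 45.6% of the 1000 strongest and 17.2% of all 4917.

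Whether NuRD occupancy followed the strength of acetylation was examined in the H3K27ac list, divided into 5 equal groups by fold enrichment. Away from gene ends, MTA2 overlapped 20.2% (18.7 to 21.8) of the weakest group and 65.4% (63.5 to 67.2) of the strongest. CHD4 rose from 24.5% to 61.3% (59.4 to 63.2), HDAC2 from 29.8% to 66.5% and RBBP4 from 15.7% to 55.5%. Sites with all 4 subunits rose from 14.9% (13.6 to 16.3) to 46.4% (44.4 to 48.3), and FLI1 from 0.666% to 20.5% (19.0 to 22.1). Near gene ends the rise was smaller, from 12.9% to 22.3% for CHD4, from 56.6% to 68.0% for HDAC2, from 23.6% to 46.2% for MTA2 and from 26.8% to 41.0% for RBBP4. Sites with all 4 there went through 12.9%, 9.45%, 11.2%, 13.6% and 17.5% from weakest to strongest. CHD4 and sites with all 4 were lower in the second weakest group than in the weakest in both locations. Shuffling the groups 10000 times never gave a difference between the strongest and weakest group as large (two-sided permutation p = 1e-04, the smallest the shufflings can give). This held for each subunit, for sites with all 4 and for FLI1, in both locations. The shuffling describes this list only. Stronger H3K27ac peaks were also wider, which by itself raises the chance of an overlap. The median width was 1410 bp in the strongest distal group against 413 bp in the weakest, and 1073.5 bp against 369 bp near gene ends. The difference between the strongest and weakest group kept its direction and call in the 5 alternatives, but its size moved. With summits required inside the acetylation peak, the distal FLI1 difference was 7.09 points instead of 19.9, and near gene ends the difference was 29.8 points instead of 11.4 for HDAC2, 23.9 instead of 14.2 for RBBP4 and 8.36 instead of 4.65 for sites with all 4. At a −log10 p of at least 15 it was 6.20 points for HDAC2, 4.22 for RBBP4, 15.03 instead of 22.6 for MTA2, 3.06 for sites with all 4 and 1.53 instead of 2.35 for FLI1 near gene ends, and 26.2 instead of 39.8 for distal RBBP4. With −log10 p as the height it was 22.2 points for HDAC2, 30.4 for RBBP4, 15.9 instead of 9.40 for CHD4, 12.1 for sites with all 4 and 3.55 for FLI1 near gene ends, and 56.3 instead of 36.7 for distal HDAC2.

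**Figure D2:**
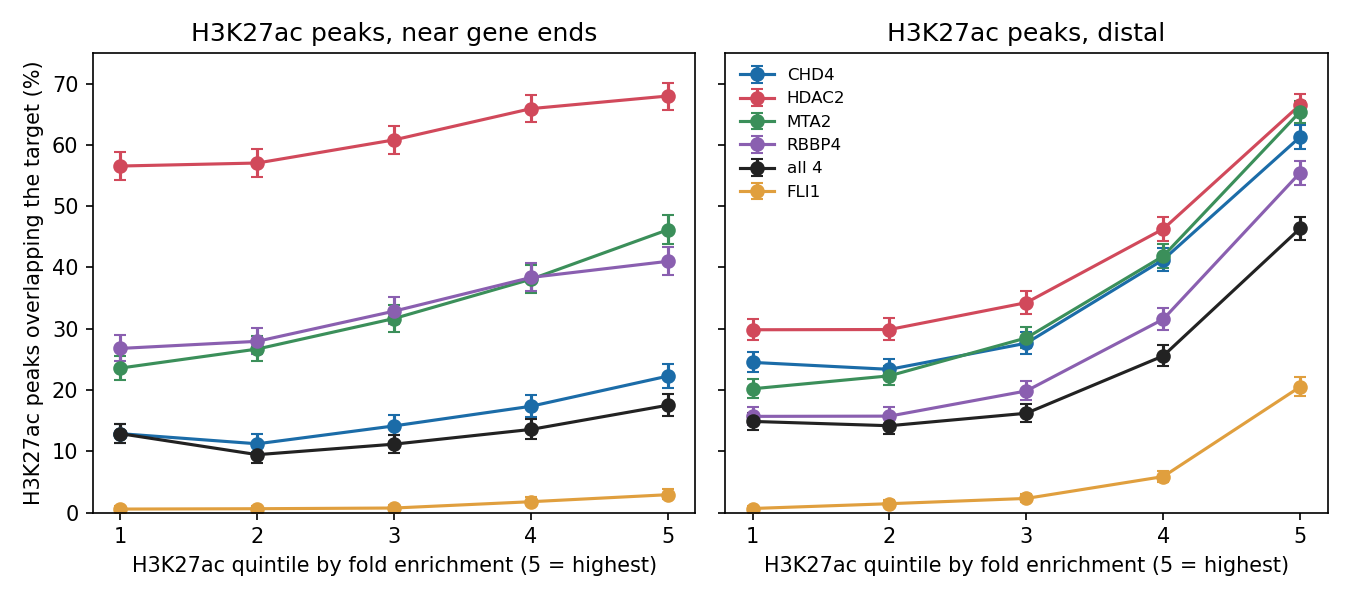
Share of H3K27ac peaks (vertical axis, percent) that overlapped each NuRD subunit, a site with all 4 subunits or FLI1, by quintile of H3K27ac fold enrichment (horizontal axis), near gene ends and away from them; bars are 95% Wilson intervals. Distal peaks with all 4 subunits rose from 14.9% in the lowest quintile to 46.4% in the highest.

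The next comparison placed NuRD beside FLI1. A FLI1 peak overlapped MTA2 in 77.2% (75.05 to 79.2), HDAC2 in 70.9% (68.6 to 73.1), CHD4 in 68.8% (66.5 to 71.1) and RBBP4 in 67.8% (65.5 to 70.1). At least 1 subunit was present at 85.6% (83.8 to 87.2) of FLI1 peaks, and 865 FLI1 peaks (55.4%, 52.9 to 57.9) overlapped peaks of all 4. The reverse shares were small, since FLI1 overlapped 8.91% of MTA2, 8.52% of CHD4, 8.10% of RBBP4 and 5.21% of HDAC2 peaks. Where peaks overlapped, FLI1 summits lay at a median of 72 bp from HDAC2 summits, 100 bp from MTA2, 123 bp from RBBP4 and 164 bp from CHD4, also without a comparison with chance. Random placement gave 0.332% to 0.781% for single subunits, with no placement as high. The calls were also kept with peaks and placements confined to chromatin with H3K27ac, H3K4me1 or H3K4me3. With the 2000 strongest peaks of each list the shares were 38.9% for CHD4, 27.5% for HDAC2, 32.0% for MTA2 and 33.3% for RBBP4, all still above their placements. The share of FLI1 peaks that overlapped a merged site with all 4 went from 57.7% (901 peaks) to 15.2% in that setting, also above its placements.

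Stronger FLI1 peaks more often carried NuRD. In the weakest quintile by −log10 p, 34.2% (29.2 to 39.6) overlapped all 4 subunits and 27.2% overlapped none. In the strongest quintile, 86.9% (82.7 to 90.2) overlapped all 4 and 0.321% none. H3K27ac overlapped 35.5% of the weakest and 88.1% of the strongest quintile. The weakest quintile was nearer to genes, with 23.003% near a gene end and 25.2% overlapping H3K4me3, against 1.28% and 0.962% in the strongest. FLI1 peaks without any subunit numbered 225, and 14.2% of them overlapped H3K27ac, against 62.5% of the 865 with all 4. The quintiles were compared by their values and carried no test.

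**Figure D3:**
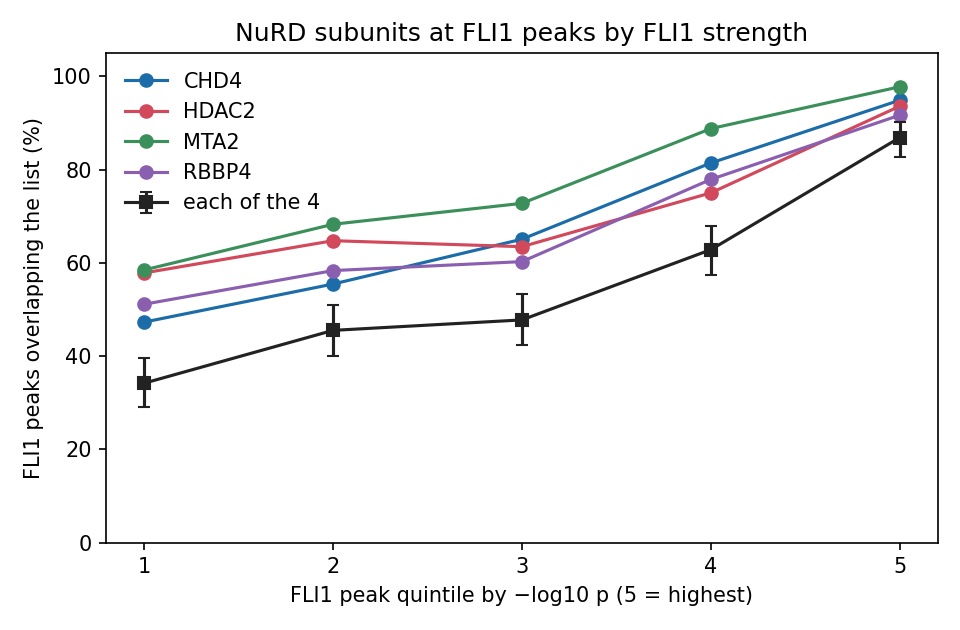
Share of FLI1 peaks (vertical axis, percent) that overlapped each NuRD list, by quintile of FLI1 −log10 p (horizontal axis); squares show FLI1 peaks that overlapped each of the 4 lists, with 95% Wilson intervals. The share with all 4 rose from 34.2% to 86.9%.

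Of all FLI1 peaks, 49.3% (46.9 to 51.8) overlapped H3K27ac, 8.01% (6.76 to 9.46) H3K4me1 and 8.46% (7.18 to 9.94) H3K4me3. Each of these exceeded all 1000 placements. No FLI1 peak overlapped H3K27me3 (0 of 1561, upper bound 0.245%), which 79 of 1000 placements also gave, so the absence did not stand apart from chance. An H3K4me1 peak covered 2.25% of distal FLI1 summits, lay within 250 bp of 21.6% (19.6 to 23.8) and within 1000 bp of 69.0% (66.5 to 71.3). For distal MTA2 summits in sites with all 4 subunits and no FLI1 the same shares were 9.35%, 48.8% (47.1 to 50.5) and 76.9% (75.4 to 78.3). The FLI1 summits were not limited to sites with all 4 subunits, so these sets are unlike. H3K27ac was within 250 bp of 64.1% of the FLI1 summits and 51.8% of the MTA2 summits. The H3K27ac share was 23.1% and the H3K4me1 share 2.05% when the FLI1 summit had to lie inside the mark, and the H3K4me3 share was 2.26% at a −log10 p of at least 15. Distal sites with all 4 subunits overlapped H3K27ac in 80.8% (77.9 to 83.3) where FLI1 was present and in 51.2% (49.4 to 52.9) where it was not. H3K4me1 overlapped 78.3% and 59.9% of the same sites.

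NuRD peaks were higher where FLI1 was present. Among distal CHD4 peaks the median fold enrichment was 6.29 (quartiles 5.12 and 7.59) at 1097 peaks that overlapped FLI1 and 4.59 (3.91 and 5.44) at 3931 peaks with H3K27ac and no FLI1. The same medians were 8.22 and 6.44 for MTA2, 6.87 and 5.09 for HDAC2, and 6.01 and 4.25 for RBBP4. None of 10000 random draws of the same size from the peaks without FLI1 reached the median with FLI1. Near gene ends the CHD4 medians were 6.13 at 35 peaks with FLI1 and 3.95 at 1277 without. The ratios there were 1.07 for HDAC2, 1.09 for both MTA2 and RBBP4, and 249, 429 and 106 of 10000 draws were as high. The sets with and without FLI1 were not matched for H3K27ac strength, and peaks with FLI1 did not need H3K27ac. FLI1 overlapped 0.666% of the weakest and 20.5% of the strongest group of distal H3K27ac peaks. The greater heights can therefore not be assigned to FLI1 apart from acetylation.

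The strongest FLI1 peak by −log10 p lay between genes on chromosome 8 (128294070 to 128294546), 551 kb from an end of MYC, the cell growth transcription factor, with a −log10 p of 193 and a fold enrichment of 13.1. The second was inside PDIA5 on chromosome 3 (123151690 to 123152332), with a −log10 p of 166 and the highest fold enrichment in the list, 30.6. The third lay 9.28 kb from an end of LRATD2 on chromosome 8 (126567500 to 126567968), and another peak, with a −log10 p of 113.0, lay 146 kb from it (126405778 to 126406317). The remaining peaks were nearest to MTX2 (318 kb), STMN4 (21.6 kb), JARID2 (138 kb), GRIK2 (inside the gene), LOC102724877 (172 kb) and MGAT4C (inside the gene). JARID2 encodes a Polycomb cofactor, STMN4 a regulator of microtubules and GRIK2 a glutamate receptor subunit. All 10 overlapped each of the 4 NuRD subunits and H3K27ac. The peaks near MYC and LRATD2 ranked lower by fold enrichment, at positions 220, 157 and 580 of 1561. They lie in a part of chromosome 8 where the local background of the peaks in the other lists was raised, as described for H3K27me3.

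Stitching distal H3K27ac peaks within 12.5 kb gave 6409 domains. Of these, 434 (6.77%) were classed as large and held 39.8% of the summed acetylation signal. FLI1 was present in 66.8% (62.3 to 71.1) of the large domains and 8.65% (7.97 to 9.39) of the others. A site with all 4 subunits was present in 84.6% (80.9 to 87.7) and 26.2% (25.1 to 27.3). Large domains were also longer, with a median width of 12.1 kb against 1.10 kb. Per 100 kb, FLI1 peaks numbered 5.56 in large domains and 3.46 in the others. CHD4 peaks numbered 19.4 and 20.4, HDAC2 peaks 15.5 and 21.5, MTA2 peaks 15.3 and 19.6, RBBP4 peaks 14.5 and 16.7, and sites with all 4 subunits 8.88 and 8.68. Domain widths include the gaps between stitched peaks, up to 12.5 kb, and only peaks that started inside a domain were counted. The densities of long and short domains are thus not directly comparable. With all H3K27ac peaks stitched, 753 domains were large and 47.7% of them held FLI1. These shares carried no test.

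The highest-ranked large domain overlapped LOC124905135 on chromosome 22 (46052302 to 46082132), with 8 HDAC2 peaks and no FLI1 peak. The second lay 28.6 kb from CRB2 on chromosome 9, and the third overlapped BMF, a pro-apoptotic gene, on chromosome 15 (40044692 to 40107323), with 14 CHD4 peaks. The fourth lay 47.0 kb from NKX2-2, a homeobox gene that the fusion is known to activate, on chromosome 20 (21552673 to 21586643). It held 3 FLI1 peaks, 6 CHD4 peaks and 4 peaks of each other subunit. The remaining domains were inside DLG2, HOOK1 and GLG1 or nearest to HMCN1, ANKRD9 and DAD1. FLI1 had at least 1 peak in each of the 10 domains except the first.

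Gene lists fixed beforehand were then compared with random lists of equal size from 19974 protein-coding genes. The random lists were not matched for H3K4me3 or H3K27ac, so an excess of a subunit can go with marked gene ends alone. Of 35 genes known to be activated by EWSR1::FLI1, 22 had a FLI1 peak within 100 kb of a gene end, against 4.28 in random lists (permutation test, adjusted p = 0.0026). Their gene ends carried CHD4 in 17 (3.71 in random lists, permutation adjusted p = 0.00293), HDAC2 in 23 (13.7, permutation adjusted p = 0.0211), MTA2 in 15 (7.32, permutation adjusted p = 0.0366) and RBBP4 in 20 (7.77, permutation adjusted p = 0.00293). H3K27ac was present in 26, H3K4me1 in 10 and FLI1 itself in 4, each more than in random lists, with permutation adjusted p of 0.00501, 0.00688 and 0.00425. With windows of 500 bp MTA2 was at 14 of these genes, FLI1 at 2 and H3K4me1 at 3, and these calls were lost, as were those of MTA2 (13) and FLI1 (2) when only gene ends with H3K4me3 counted. At a −log10 p of at least 15 RBBP4 was at 10 of them and the call held. Over the alternatives the permutation adjusted p ran from 0.0018 to 0.103 for MTA2, to 0.241 for FLI1 and to 1 for H3K4me1. The strongest FLI1 peaks within reach were 56.0 kb from CAV1, a membrane scaffold gene (−log10 p of 100.1), 37.9 kb from IL1RAP, an interleukin receptor subunit (99.5), 30.3 kb from PAPPA (88.5) and 69.2 kb from MYC (72.9), the last in the part of chromosome 8 with raised local background. Others lay 36.1 kb from PPP1R1A, inside PRKCB, a protein kinase C gene, 53.4 kb from NKX2-2, and 2.21 kb from LIPI, where the same peak was 2.66 kb from RBM11. The peak inside EZH2, the Polycomb methyltransferase gene, had a −log10 p of 58.7. Of these peaks all but that in EZH2 overlapped all 4 subunits and H3K27ac. The EZH2 peak overlapped CHD4, HDAC2 and MTA2.

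Of 12 genes known to be repressed by the fusion, 1 had a FLI1 peak within 100 kb. That was TGFBR2, a receptor of transforming growth factor beta, with a FLI1 peak at 39.3 kb, and no target differed from random lists in this group. Of the 6 core transcription factor and fusion genes of Ewing sarcoma, 3 had FLI1 within 100 kb (permutation adjusted p = 0.237), with the strongest peak inside KLF15 (−log10 p of 90.5), and the others near NKX2-2 and EWSR1.

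The HOX genes, which pattern the body axis, carried CHD4 more often than random lists. Of 39 HOX genes, 15 carried CHD4 (4.10 in random lists, permutation adjusted p = 0.00293), 18 MTA2 (permutation adjusted p = 0.00425) and 18 RBBP4 (permutation adjusted p = 0.0104). HDAC2 was at 22, against 15.3 in random lists, which missed the threshold (permutation adjusted p = 0.1755). The MTA2 and RBBP4 calls were lost at a −log10 p of at least 15 (7 and 9 genes), with windows of 500 bp (13 and 14) and with only gene ends that carry H3K4me3 (15 each), with a permutation adjusted p over the alternatives of 0.0018 to 1 for MTA2 and 0.0018 to 0.116 for RBBP4. H3K4me1 was present at 16 (8 with windows of 500 bp and 7 with only gene ends that carry H3K4me3, where the call held) and H3K27me3 at 6 (0.940 in random lists, permutation adjusted p = 0.00624). HOXA5 and HOXA10 were among those with CHD4, and HOXA3, HOXA4, HOXA5 and HOXA7 among those with H3K27me3. None had a FLI1 peak within 100 kb, against 4.77 in random lists, which missed the threshold (permutation adjusted p = 0.0741), and 9 had FLI1 within 250 kb. HOX genes adjoin each other and share gene ends and peaks, as HOXC4, HOXC5 and HOXC6 did, so random lists of scattered genes understate the chance spread. At a −log10 p of at least 15, 3 HOX genes carried H3K27me3 and the difference was lost (permutation adjusted p = 0.169, against 0.0026 to 0.0144 in the other alternatives).

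Of 20 DNA damage and cell cycle genes, 18 carried HDAC2 (7.85 in random lists, permutation adjusted p = 0.00293), 14 RBBP4 (permutation adjusted p = 0.00293) and 12 MTA2 (permutation adjusted p = 0.00688), among them the checkpoint kinase genes ATM and ATR. At a −log10 p of at least 15 RBBP4 was at 8 and the call held, and with windows of 500 bp MTA2 was at 9 and the call was lost (permutation adjusted p = 0.0961, and 0.00468 to 0.0961 over the alternatives). CHD4 was present at 3, namely CHEK2, GADD45A and PARP1. H3K4me3 was present at all 20 and H3K27ac at 18. Among all protein-coding genes 57.0% carried H3K4me3, and HDAC2 was present at 66.2% of genes with H3K4me3 and no H3K27me3. The random lists therefore understate how often genes with H3K4me3 carry HDAC2. All 15 genes for NuRD subunits carried H3K4me3 (permutation adjusted p = 0.00501) and 6 carried CHD4 (1.58 in random lists, permutation adjusted p = 0.0366), namely CHD3, CHD4, CHD5, MTA1, MTA3 and GATAD2B. That CHD4 call was lost at a −log10 p of at least 15 (4 genes), with windows of 500 bp (3) and with only gene ends that carry H3K4me3 (5), with a permutation adjusted p over the alternatives of 0.016 to 0.7003. Of 15 housekeeping genes, 14 carried H3K27ac and 14 H3K4me3, with permutation adjusted p of 0.00293 and 0.0301. H3K4me3 was present at none of 8 skeletal muscle genes such as MYOD1 (4.57 in random lists, permutation adjusted p = 0.0185) and none of 10 blood cell genes (5.69, permutation adjusted p = 0.00501). No target differed from random lists for the developmental regulator, neural crest and neuronal, mesenchymal or epithelial genes. FLI1 lay within 100 kb of 3 of the 24 developmental regulators (PAX3, PAX9 and OTX2), 3 of 16 neural genes, 3 of 16 mesenchymal genes and 0 of 8 epithelial genes. It lay within that distance of 2 of 15 NuRD genes, 1 of 8 muscle genes, 2 of 10 blood cell genes, 4 of 15 housekeeping genes and 2 of 20 DNA damage and cell cycle genes, and none of these counts differed from random lists. In all, 21 of 117 list and target combinations were higher than random lists and 2 lower. The number higher was 14 with windows of 500 bp, 16 with only gene ends that carry H3K4me3, 17 at a −log10 p of at least 15 and 24 with windows of 2500 bp, and the number lower was 2 or 3.

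H3K27me3 and NuRD were compared at the ends of all 19974 protein-coding genes. Genes with H3K4me3 and no H3K27me3, here called H3K4me3 alone whatever their H3K27ac, numbered 11114. Of these, 66.2% (65.4 to 67.1) carried HDAC2, 38.0% RBBP4, 35.7% MTA2, 17.1% (16.4 to 17.8) CHD4 and 68.4% H3K27ac. The 274 genes with H3K4me3 and H3K27me3 carried HDAC2 in 47.1% (41.3 to 53.0), MTA2 in 17.5%, RBBP4 in 13.1% (9.64 to 17.7), CHD4 in 9.49% (6.56 to 13.5) and H3K27ac in 4.74%. The 200 genes with H3K27me3 and no H3K4me3, here called H3K27me3 alone, carried HDAC2 in 8.50% and CHD4 in 1%. The 8386 genes with a peak of neither mark carried HDAC2 in 3.68% and CHD4 in 2.07%. The H3K27me3 peaks covered only 2.38 Mb, so genes without such a peak may still carry the mark. Among the genes with both marks, HDAC2 was above and RBBP4 below random gene sets, with 35 and 2 of 10000 draws as far out. CHD4 (3288 draws as low) and MTA2 (963) stayed within them. The random sets came from all protein-coding genes (HDAC2 at 39.1%), of which 8386 had neither mark. Beside the genes with H3K4me3 alone, each subunit was less frequent at the genes with both marks, a difference that was not tested. These classes also differed in H3K27ac, at 68.4% and 4.74%, so the difference does not belong to H3K27me3 alone. At a −log10 p of at least 15 HDAC2 was present at 40% of such genes and no longer stood apart, and MTA2, at 9.70%, lay below the random sets. RBBP4 was then present at 4.85% of these genes and at 14.9% of those with H3K4me3 alone, and CHD4 at 10.7% of the latter. At the genes with H3K27me3 alone CHD4 ranged from 0.543% to 2.37% over the alternatives.

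The H3K27me3 list was concentrated on chromosome 8, with 950 peaks (27.8% of those on chromosomes 1 to 22 and X), against 3.58% of protein-coding genes. Chromosome 7 held 11.3% and chromosome 18 none. In the 8 other lists the recovered background was 1.15 to 1.23 times the autosomal median on chromosome 7. On chromosome 18 it was 0.519 to 0.619 times. Chromosomes 4, 14 and X, at 0.535 to 0.832 times, held 0.732%, 0.205% and 0.0585%. Chromosome 21 went the other way, at 1.003 to 1.25 times with 0.117%. The relation was not tested, and absence on chromosome 18 cannot be told from a lack of depth. Of the 950 peaks, 919 lay between 119 and 143 Mb, 904 of them in 18 windows of 1 Mb with at least 10 peaks. In these windows the local background recovered from each peak's fold enrichment and −log10 p was 2.62 to 3.42 times the autosomal median in the 8 other lists. On the rest of chromosome 8 the ratio for the same lists was between 0.831 and 0.970. That remainder includes 5 windows of the span with 0 to 4 H3K27me3 peaks, where the median ratio per window was 2.50 to 4.08, against 1.75 to 4.23 in 16 of the 18 windows. The H3K27me3 peaks in the windows had a median fold enrichment of 4.95 against 6.59 elsewhere. The region with the greatest covered length, 25.3 kb, lay 80.4 kb from C8orf90 (141576084 to 141622079), and the second lay inside FER1L6 (124049930 to 124073373). Of the 10 longest regions, those near LPCAT1 on chromosome 5 (1599466 to 1644494) and over SP8, a limb and brain patterning factor, on chromosome 7 (20773054 to 20797607) lay on other chromosomes. The others lay near C8orf90, TSNARE1 and ZHX2.

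**Figure D4:**
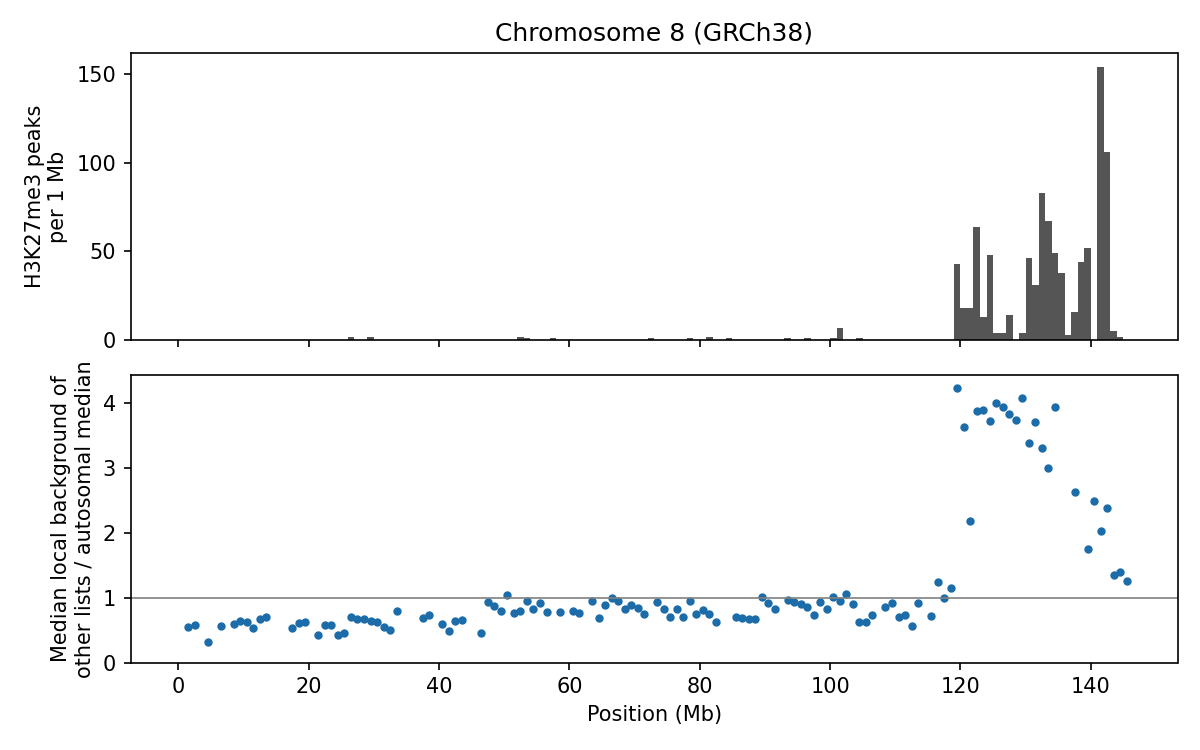
Number of H3K27me3 peaks per 1 Mb window along chromosome 8 (top, horizontal axis in Mb) and the median local background of the peaks of the 8 other lists in each window, relative to the autosomal median of each list (bottom, each point a window with at least 5 peaks). Between 119 and 143 Mb lay 919 of the 950 H3K27me3 peaks, 904 of them in 18 windows, and the background was raised there also in 5 windows with 0 to 4 such peaks.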

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

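Over 744 recomputed values of 136 results, 701 kept their direction and call or stayed within the set range, 22 lost their call, 4 gained one and 17 moved, and none reversed. Removal of chromosome 8 and the restriction to gene ends with H3K4me3 were chosen after seeing the data. The first changed no call and the second ended 5, given with the gene lists. The pairwise NuRD overlaps, rerun in 1 direction of each pair, kept their call under each alternative run for them. The overlaps of FLI1 with each subunit and with H3K27ac, and the higher distal NuRD peaks at FLI1 sites, did so too. FLI1 peaks with CHD4 ranged from 38.9% to 79.4%. The increase of H3K4me1 with the number of subunits was not kept: from 1 to 4 subunits the shares were 11.97%, 9.75%, 8.44% and 9.31% with the midpoint inside the mark and 12.1%, 10.5%, 10.1% and 15.8% with an overlap of 50%, each still above its placements. Differences by H3K27ac strength kept their call, and near gene ends ranged from 6.20 to 29.8 points for HDAC2, 4.22 to 30.4 for RBBP4 and 3.06 to 12.1 for sites with all 4. At a −log10 p of at least 15, peak numbers fell to 8796 for CHD4, 6386 for RBBP4, 972 for FLI1, 19953 for H3K4me1 and 1341 for H3K27me3, and sites with all 4 subunits to 2683, since fewer peaks remain. The same threshold gave 11.7% active promoters, 39.9% active enhancers and 14.5% unmarked sites among sites with all 4 subunits. It ended the calls for FLI1 near gene ends (3.09%), for low H3K27me3 at sites with all 4 subunits (0.112%) and at CHD4 peaks (0.0796%), for H3K27me3 at HOX genes (3 genes, permutation adjusted p = 0.169, against 0.0026 to 0.0144 otherwise) and for HDAC2 at genes with H3K4me3 and H3K27me3 (40%), and MTA2 at the latter genes became lower (9.70%). Calls of gene lists were lost at that threshold for CHD4 at NuRD genes (4 genes) and for MTA2 (7) and RBBP4 (9) at HOX genes. With windows of 500 bp they were lost for MTA2 (14), FLI1 (2) and H3K4me1 (3) at fusion-activated genes, CHD4 at NuRD genes (3), MTA2 (13) and RBBP4 (14) at HOX genes and MTA2 at DNA damage and cell cycle genes (9). With only gene ends that carry H3K4me3 they were lost for MTA2 (13) and FLI1 (2) at fusion-activated genes, CHD4 at NuRD genes (5) and MTA2 (15) and RBBP4 (15) at HOX genes. The permutation adjusted p of these lost calls ran from 0.0523 to 1, and the lowest for the same combinations over the alternatives from 0.0018 to 0.016. The 2000 strongest peaks per list left 364 sites with all 4 subunits. With the site's midpoint inside the mark, the H3K27me3 share was 0.0407% at these sites and 0.148% at sites with 2 subunits, and both calls were lost. Low H3K27me3 became a call at MTA2 peaks with the summit inside the mark (0.0594%) or an overlap of 50% (0.0743%), and at RBBP4 peaks at a −log10 p of at least 9 (0.0933%). Active promoters were 14.8% with a window of 500 bp and 17.2% with 2500 bp. Stitching all H3K27ac peaks gave 753 large domains, 76.1% with all 4 subunits and 47.7% with FLI1, and summed fold enrichment alone gave 74.4% and 54.8%. Beyond list length the cause was not tested. The GGAA repeat results and their alternatives were not run without a genome sequence. Unknown read depth limits each statement that a peak was absent. No paired analysis was possible because each target had 1 list.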

Other observations

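Tests of the fold enrichment of chromosome 8 peaks, of H3K4me1 beside FLI1 and of narrow FLI1 intervals were chosen after related results had been seen, and the bounds of the last were rewritten after a first run. Chromosome shares outside chromosome 8 were also uneven. Chromosome 6 held 9.03% of CHD4 peaks and 8.87% of RBBP4 peaks, against 5.25% of protein-coding genes. Its share was 9.24% for H3K4me1, 8.06% for FLI1, 7.89% for MTA2, 7.70% for HDAC2 and 5.90% for H3K4me3. The recovered background there was 1.15 (CHD4) to 1.25 (H3K4me3) times the autosomal median in the lists other than H3K27me3, where it was 0.952. Chromosome 19 held 3.07% of CHD4, 2.47% of RBBP4 and 1.45% of H3K4me1 peaks, against 7.26% of genes. HDAC2 and MTA2 together, without CHD4 or RBBP4, made up 2399 sites with H3K4me1 at 30.8% and H3K4me3 at 48.0%. Sites with CHD4, MTA2 and RBBP4 but no HDAC2 numbered 698, with FLI1 at 9.46%, H3K4me1 at 53.4% and H3K4me3 at 7.74%.

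H3K27me3 peaks gathered on chromosome 8, where 919 lay between 119 and 143 Mb, 904 of them in 18 windows of 1 Mb. Extra copies of this region are a candidate explanation: the median over the 8 other lists of the local background there was 3.21 times the autosomal median, and all 8 lists exceeded 1.3. The control of each list is unknown, so the 8 lists may not be independent. A related explanation, that local depth lifted weak enrichment past the p threshold, also had the values it needs, since the median fold enrichment in the windows was 0.752 times that elsewhere. This is not separate evidence. The median −log10 p was 14.6 in the windows and 13.7 elsewhere, and at a similar −log10 p a raised background itself lowers the fold enrichment. Both explanations were judged from peak values and not from reads. In the span, 5 windows with a background of 2.50 to 4.08 times the median held only 0 to 4 H3K27me3 peaks. Raised background thus did not go with many peaks everywhere, and no biological explanation was tested. The peaks near MYC and LRATD2 lie in the same region, so their rank by −log10 p may owe part to copy number.

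H3K4me1 peaks seldom overlapped distal FLI1 peaks. Interval width alone does not account for the gap between FLI1 and the subunits. Distal subunit peaks without FLI1, taken at the same width, overlapped H3K4me1 in at least 22.5% (RBBP4, 21.6 to 23.4). For FLI1 the share was 8.22% (6.90 to 9.76). Each list was cut around its own summits, so width may still play a part in the low FLI1 share. A position beside the interval may account for part of the low share. Within 1 kb, 69.0% of distal FLI1 summits had H3K4me1, and within 250 bp 21.6%. Distal MTA2 summits in sites with all 4 subunits and no FLI1 had it in 76.9% and 48.8%. The FLI1 summits were not limited to sites with all 4 subunits, so these sets are unlike. A wider window can only hold more, so the rise from 250 bp to 1 kb alone shows no position particular to FLI1. At 1 kb the FLI1 share was still the lower in these unlike sets. Among distal sites with all 4 subunits it went the other way, with H3K4me1 at 78.3% with FLI1 and 59.9% without. The widths of those sites were not compared. Whether nucleosomes are displaced or carry other methylation at FLI1 summits stays open, and no biological explanation was tested.

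HDAC2 lay near gene ends more often than the other subunits in the full lists. With 2000 peaks per list its share was 1.46 times the mean of the other 3 subunits, between the bounds set beforehand of 1.2 for an effect of list length and 1.5 against it, and the MTA2 share (36.3%) was above that of HDAC2 (29.3%). List length and a preference of HDAC2 cannot be told apart here, since the ratio lay between the bounds. Narrowly missed peaks of the other subunits remain a candidate explanation for HDAC2-only sites near gene ends, where the median HDAC2 fold enrichment was 0.867 times that at sites with all 4 subunits. No biological explanation was tested.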
